A study of Arabidopsis thaliana with 21 samples.

How the data were processed

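The deposited files hold raw counts: each line gives a distinct small RNA sequence of 15 to 42 nt and its read count, with no normalization, as deposited. Per the labels, total RNA came from immature inflorescences and the libraries were made with the TruSeq Small RNA kit and read on a HiSeq instrument; the extraction protocol in the labels of each library names both immature Arabidopsis inflorescence and maize leaves. The submitters' notes name TAIR10; the aligner and the trimming tool are not given in the sources used here. The series text calls the 3 replicates of each line biological replicates. Replicate libraries of a group differed by more than counting error (chi-square per degree of freedom 2.56 to 13.9), so none was a copy of another.

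Sequences of 18 to 28 nt were matched without mismatch to the TAIR10 genome, including both organelles; 75.7% to 82.8% of reads matched in the Ws-background groups and 85.2% to 88.8% in the triple-mutant groups. Reads from ribosomal, transfer, small nuclear and small nucleolar RNA genes and from organelles were set aside, and the kept reads of each library served as its library size. The tested features were 500 bp windows, counted with 23 to 24 nt reads that match exactly 1 place, and 4 lists fixed before the data were examined. The lists were 34 microRNAs (exact sequence), 8 TAS genes (21 to 22 nt), 13 targets of RNA-directed DNA methylation with 2000 bp upstream (23 to 24 nt) and 8 ARGONAUTE genes (18 to 28 nt), the gene lists counted with reads matching 1 place only. The element AtSN1 was dropped from the target list, because the identifier written for it belongs to another locus in this annotation. The annotation has no class for transposon genes, so windows over its pseudogene models were used for them, which departs from the plan. Models whose note calls them a pseudogene were left out of this class. Each window had a single class: pseudogene model, else protein-coding body, else 1 kb upstream, else other. Arms and pericentromeres were a separate split. AGO3, AGO7, AGO8, MEA, EVD, TAS4 and miR397a had too few reads to be tested.

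The 26392 features that passed filterByExpr were fitted by edgeR's quasi-likelihood method with 1 term per genotype over the 21 libraries, with a common biological coefficient of variation of 22.2%. P values were adjusted by the Benjamini-Hochberg method over all features in each comparison, and adjusted p below 0.05 was called. TMM factors, DESeq2 with its own size factors, microRNA counts as library size and the other alternatives were tried as stated at the end. Power was checked on simulated counts of all 21 libraries, with a common mean per feature. Known changes were set in 200 features of the simulated ago4-4 libraries. For ago4-4 against Ws, edgeR found 0 of 67 features at 1.5-fold, 7 of 67 at 2-fold (10.4%) and 41 of 66 at 4-fold (62.1%). There were 3 false calls among 22150 features. Small changes are therefore missed in most features. From 305 to 2206 tested features had no read in either group of a comparison; their fold is 0 by construction and none was called. Without them the pseudogene medians were 0.52, -0.52, -0.05, 0.43, 0.55, -0.29, 0.11 and 0.39 in the order of the comparisons in the report.

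Window classes were tested by limma's camera with a preset correlation of 0.01 and again with an estimated one, and by fry. Named windows were chosen by a rule fixed before the data were examined. In each comparison, windows with adjusted p below 0.05, a mean of at least 50 counts over the 6 libraries and no overlap between the groups' CPM values were ordered by the size of the log2 change. Windows within 2000 bp of one already taken were dropped, and the first 8 lower and first 4 higher were kept. No overlap arises by chance in 10% of features with 3 libraries against 3. A window was named by the gene it overlaps, else by the nearest gene within 2000 bp, else by its coordinates; each feature of the 4 lists was named as well. Of these, the text prints a selection. Where a group had 0 reads, the fold was computed against 3 counts over the group and is given as a lower bound; with 1 to 3 reads the ratio has a 95% counting interval. Floors and intervals cover counting error only, since PCR copies are not independent molecules.

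Chromosome segments were traced at 18323 sites, called informative, where at least 10 of the 23 to 24 nt reads pooled over the 6 Ws and ago4-4 libraries carried a base other than the reference and at most 10% carried the reference base, in 121 bins of 1 Mb. Alleles in a bin were taken to differ where the compared libraries spanned over 50 points. The high share of Ws alleles in those 6 libraries follows from this choice; the 6 libraries of ago4-4 with a transgene were not used in it (99.59% to 99.64%). The share of 24 nt reads and of a first A was tested over the 7 groups by permuting libraries (100000 resamples) and in the 8 comparisons by exact two-sided permutation tests, 16 in all. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the package data.table, 1.17.8.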

Results

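Small RNAs were sequenced from immature inflorescences of Arabidopsis thaliana in 7 genotypes with 3 biological replicates each, giving 21 libraries. Ws is a wild-type laboratory accession, and ago4-4 is a null mutant of ARGONAUTE4 (AGO4) in that accession. AGO4 is the ARGONAUTE protein that binds 24 nt small interfering RNAs in RNA-directed DNA methylation. The ago4-4/6-2/9-1 line, called the triple mutant here, also lacks AGO6 and AGO9, which belong to the same ARGONAUTE clade, and its label gives a mixed Col-0/Ws background. Each mutant was also studied with a wild-type AGO4 transgene (wtAGO4) and with AGO4-D742A, a form that cannot slice RNA. The files held 7580206 to 20173947 reads per library (median 12559937). After matching to the genome and removing structural and organelle RNA, 3736855 to 7950197 reads per library were kept, and levels are given as counts scaled to these kept reads (CPM). The ago4-4 files held 17826385 to 20173947 reads, against 10045042 to 12391059 in Ws.

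The first question was how the size and first base of the small RNAs depended on AGO4. The 24 nt class made up 47.1% ± 1.81 (SD, n = 3) of the 20 to 25 nt reads in Ws and 39.95% ± 1.06 in ago4-4. Structural RNA made up 9.97% ± 1.72 of matched reads in Ws and 13.1% ± 3.36 in ago4-4, and organelle RNA 9.33% ± 1.17 and 13.4% ± 2.81; ago4-4 replicate 2 stood apart from the other 2 with 9.29% and 10.1%, at a 24 nt share of 40.6%. The 24 nt class made up 46.3% ± 1.17 with wtAGO4 and 42.4% ± 0.540 with AGO4-D742A. In the triple mutant the share was 41.9% ± 2.08, and it was 45.1% ± 2.61 with wtAGO4 and 45.7% ± 0.918 with AGO4-D742A. The wtAGO4 libraries overlapped those of the triple mutant (exact permutation p = 0.2), and the AGO4-D742A libraries did not (exact permutation p = 0.1). The triple mutant lay below ago4-4 with all reads in the file (37.6% and 39.6%). It also did with each distinct sequence counted once (51.3% and 52.8%). With 18 to 28 nt reads as the total it lay above (37.1% and 34.6%). With distinct sequences AGO4-D742A in the triple mutant lay below wtAGO4 (53.5% and 55.2%), and above it in the other settings. The main shares count only reads that match the reference, which were a smaller part in the Ws background. With all reads in the file the share was 47.97% in Ws, and 46.5% and 41.9% in ago4-4 with wtAGO4 and AGO4-D742A. In the triple mutant it was then 40.9% with wtAGO4 and 41.6% with AGO4-D742A. The 7 groups differed by a permutation test of the F ratio (F = 8.27, p = 0.00082). Reads of 22 nt made up 4.63% in Ws, 5.68% in ago4-4 and 9.30% in the triple mutant. In the triple mutant they made up 8.08% with wtAGO4 and 8.66% with AGO4-D742A. The triple-mutant lines also differ from the other lines in accession, so differences between them cannot be assigned to AGO6 and AGO9.

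The share of 24 nt reads that begin with A, the base that the AGO4 clade prefers, separated the genotypes more clearly. It was 59.0% ± 0.325 in Ws, 52.5% ± 0.974 in ago4-4 and 46.5% ± 0.549 in the triple mutant (SD, n = 3). With wtAGO4 it was 57.5% ± 0.0153 in ago4-4 and 55.4% ± 1.51 in the triple mutant. With AGO4-D742A it was 53.1% ± 0.184 in ago4-4 and 49.98% ± 0.356 in the triple mutant. Reads beginning with C made up 12.3% of 24 nt reads in Ws, 17.2% in ago4-4 and 19.2% in the triple mutant. The step from ago4-4 to the triple mutant also changes the accession, so it cannot be assigned to AGO6 and AGO9. The 7 groups differed by a permutation test (F = 103, p = 1e-05, the smallest that 100000 resamples can give). The 8 comparisons between 2 groups were also tested by exact two-sided permutation, which cannot go below p = 0.1 with 3 libraries against 3. The difference of 0.595 points between AGO4-D742A and ago4-4 gave an exact p = 0.4, and it was -0.116 points when only reads matching 1 place were used. With each distinct sequence counted once it was 1.32 points, from 45.75% ± 0.2499 to 47.07% ± 0.108, with no overlap between the libraries (exact p = 0.1).

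**Figure D1:**
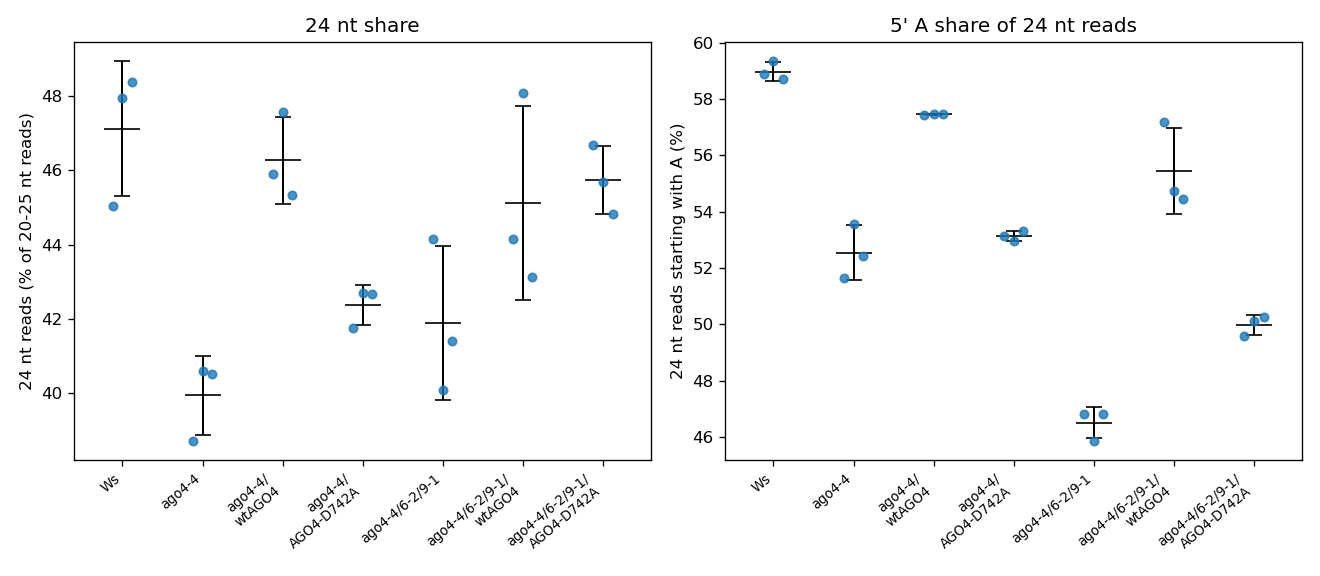
The left panel plots the 24 nt share of 20 to 25 nt reads (%) and the right panel the share of 24 nt reads beginning with A (%), with 1 point per library, a bar at the mean and error bars of 1 SD (n = 3); neither axis starts at 0. In the right panel the 3 triple-mutant libraries lie lowest, around 46.5%, and the 3 Ws libraries lie highest, around 59.0%.

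The AGO4 gene itself (TAIR10, chromosome 2, 11536502 to 11542391) gave few small RNAs outside the AGO4-D742A lines. Its 18 to 28 nt reads stood at 4.66 ± 1.63 CPM in Ws, 2.31 ± 0.403 in ago4-4 and 5.23 ± 1.48 with wtAGO4 (SD, n = 3). With AGO4-D742A they stood at 61.0 ± 2.12 CPM in ago4-4 and at 17.3 ± 2.60 CPM in the triple mutant. The rise over ago4-4 was 4.71 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 9.9e-12). Of the 847 AGO4 reads in ago4-4/AGO4-D742A, 45.5% were antisense and 73.9% were 21 or 24 nt long. In Ws, 0 of 71 AGO4 reads were antisense, but antisense reads were not particular to AGO4-D742A: they made up 42 of 52 in ago4-4, 37 of 56 in the triple mutant, 31 of 76 in ago4-4/wtAGO4 and 36.0% and 37.3% in the triple mutant with wtAGO4 and with AGO4-D742A. Small RNAs from a gene do not measure its messenger RNA, so these values do not check that ago4-4 is a null. Only 1 read matching the reference covered the middle base of the codon changed in D742A (position 11537780), and no read had that base changed from A to C. Reads with other changes there were not searched for, so the substitution itself could not be checked either.

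**Figure D2:**
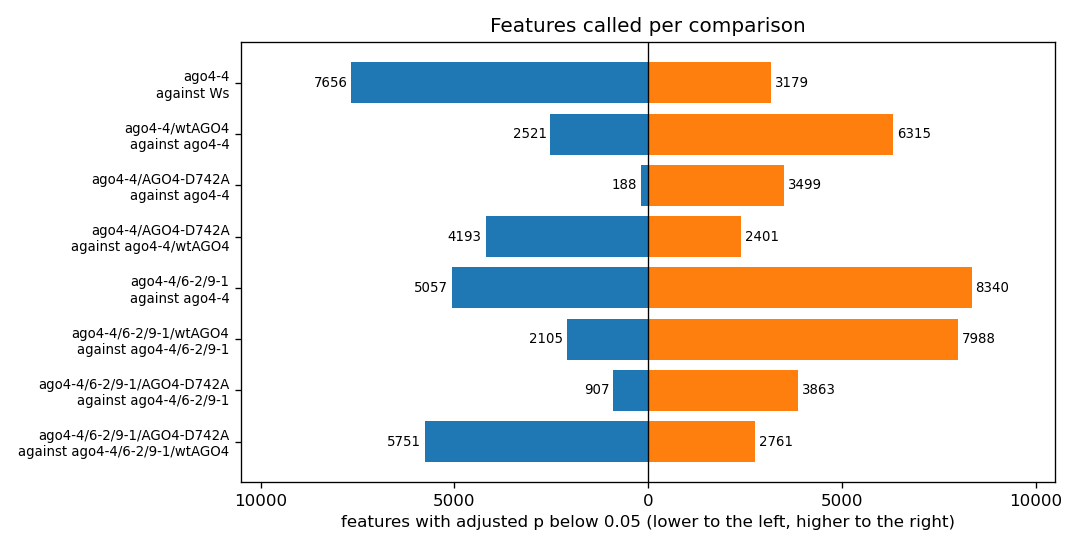
Horizontal bars give the number of features called lower (left) and higher (right) in the group named first, for each of the 8 comparisons, at an adjusted p below 0.05 of 26392 features tested. The 2 comparisons of AGO4-D742A against its own mutant background have the fewest features called lower, 188 and 907.

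The comparison of ago4-4 with Ws asked which small RNAs depend on AGO4. In ago4-4, 7656 of 26392 features fell and 3179 rose (edgeR quasi-likelihood test, adjusted p below 0.05). Windows within 1 kb upstream of protein-coding genes mostly fell: 2055 of 3863 were lower and 169 higher, with a median log2 change of -1.30. Of the windows over pseudogene models, used here in place of transposon genes, 515 of 7822 were lower and 1671 higher (median 0.37). Most were not called either way. Chromosome arms held 4030 lower and 810 higher windows of 9572, and the pericentromeres 3620 lower and 2366 higher of 16764.

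Several windows near genes lost all of their reads in ago4-4. The window upstream of PRA1.F4, which encodes a prenylated RAB acceptor (TAIR10, chromosome 3, 4494001 to 4494500), stood at 59.6 ± 3.42 CPM in Ws and 0 in ago4-4, at least 446-fold lower. The window upstream of CLC-B, a chloride channel family gene (chromosome 3, 10023001 to 10023500), was at least 491-fold lower, from 65.4 ± 6.37 CPM. A window over AT1G55430 (chromosome 1, 20699501 to 20700000) was also at least 491-fold lower. A window downstream of the noncoding gene AT1G06983 (chromosome 1, 13837501 to 13838000) was at least 603-fold lower, from 80.6 ± 3.87 CPM. Among windows that rose, that upstream of the pseudogene AT2G03650 (chromosome 2, 1110501 to 1111000) was 10.8-fold higher at 46.0 ± 8.65 CPM, and that upstream of the pseudogene AT1G34230 was 7.91-fold higher.

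Of 11 tested RNA-directed DNA methylation targets, 5 fell and 1 rose, and the counts were the same adjusted over the list alone. Reads at FWA, a homeodomain gene silenced by methylation, fell from 8.79 ± 1.47 to 2.02 ± 0.865 CPM (log2 change -2.10, adjusted p = 1.5e-06). Reads at the Mutator-like element AtMU1 fell from 35.9 ± 2.24 to 15.1 ± 2.71 CPM (log2 change -1.24). SDC, an F-box gene, fell by 0.51 on the log2 scale, and the DNA demethylase gene ROS1 by 0.86. The call at FLC, a MADS-box floral repressor, rested on Ws replicate 2, which held 188 of its 190 Ws reads; without it the log2 change was -0.16. EPF2, which encodes a stomatal patterning peptide, rose by 0.68. Of 33 tested microRNAs, 0 fell and 2 rose (1 adjusted over the list alone), miR399b by 1.00 and miR396a by 0.65. Of 7 tested trans-acting siRNA (TAS) genes, 0 passed the test and 0 had an unadjusted p below 0.05 by edgeR, and of 5 tested ARGONAUTE genes AGO4 fell by 1.00.

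The set test over window classes (camera) called 38 of 48 class results over the 8 comparisons with a preset correlation, and 4 with an estimated correlation, each of them for pseudogene windows. Here the rise of pseudogene windows had an adjusted p = 0.0343 with an estimated correlation, upstream windows an adjusted p = 0.0804 and the arms an adjusted p = 0.091. The pericentromere class had a median of 0, was called up by camera relative to other windows and went down on balance by fry, and its adjusted p was 0.091 with an estimated correlation. With TMM scaling the split became 6731 lower and 5396 higher, and 2099 features were higher without ago4-4 replicate 2. Leaving out 1 library at a time ended the call at ROS1 in each of 6 fits (log2 change -0.99 to -0.70), at SDC without Ws replicate 2, ago4-4 replicate 1 or ago4-4 replicate 3 (-0.41, -0.47 and -0.47), at AGO4 without Ws replicate 1 (-0.72) and at miR396a without Ws replicate 2, Ws replicate 3 or ago4-4 replicate 2 (0.63, 0.59 and 0.41). The calls at AGO4, SDC and ROS1 also ended with TMM (-0.72, -0.21 and -0.56), and those at miR396a, SDC and ROS1 with miRNA scaling (0.59, -0.56 and -0.91). With no filter on low counts AGO4, SDC, ROS1 and EPF2 did not pass (adjusted p = 0.0541, 0.438, 0.219 and 0.0590 by edgeR), and ROS1 did not with DESeq2 (-0.83).

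The wild-type transgene in ago4-4 asked what AGO4 brings back. With wtAGO4, 6315 features rose and 2521 fell relative to ago4-4. Upstream windows again moved most, with 1785 of 3863 higher and 126 lower (median log2 change 0.95), and of the pseudogene windows 1383 of 7822 were lower and 346 higher (median -0.38). The window upstream of PRA1.F4 returned to 57.3 ± 1.97 CPM, at least 427-fold over ago4-4, and the window beside AT1G06983 to 88.9 ± 13.1 CPM, at least 665-fold. That upstream of CLC-B did not return and held 1 read in the 3 wtAGO4 libraries.

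Of the 11 methylation targets, 3 rose and 1 fell, and the counts were the same adjusted over the list alone. FWA rose by 1.60, AtMU1 by 0.99 and SDC by 0.63 on the log2 scale, while EPF2 fell by 0.59. Of 7 TAS genes 0 passed the test (0 at an unadjusted p below 0.05 by edgeR), and of 33 microRNAs miR399b fell by 0.61 (0 adjusted over the list alone). Of the 5 ARGONAUTE genes, AGO4 rose by 1.17 and AGO6 fell from 15 reads to 1 read. By camera, pseudogene windows had an adjusted p = 0.0343 with an estimated correlation and upstream windows an adjusted p = 0.0804.

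With TMM the split was 5854 higher and 4294 lower, with miRNA scaling it was 6509 higher and 1374 lower, and the lower count was 1501 without ago4-4 replicate 2 and 1611 without wtAGO4 replicate 1. Leaving out ago4-4 replicate 1, ago4-4 replicate 3 or wtAGO4 replicate 1 ended the call at EPF2 (log2 change -0.55, -0.58 and -0.44), leaving out wtAGO4 replicate 3 that at SDC (0.55), and leaving out ago4-4 replicate 1, ago4-4 replicate 2, wtAGO4 replicate 1 or wtAGO4 replicate 3 that at miR399b (-0.61, -0.34, -0.51 and -0.60). The call at AGO6 ended without ago4-4 replicate 3 and without wtAGO4 replicate 2 or 3 (adjusted p = 0.0512, 0.0948 and 0.0681 by edgeR), and with DESeq2 (adjusted p = 0.0542). MiRNA scaling ended the calls at EPF2 (-0.47) and miR399b (-0.43), and with no filter AGO6, miR399b, SDC and EPF2 did not pass.

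The slicing-defective transgene in ago4-4 asked what AGO4 brings back without cutting RNA. AGO4 protein was not measured here, so slicing cannot be told apart from transgene dose, silencing or line. With AGO4-D742A, 3499 features rose and 188 fell relative to ago4-4. Upstream windows rose at 973 of 3863 and fell at 23 (median log2 change 0.49), and gene bodies rose at 920 of 4853 and fell at 35. Pseudogene windows moved little, with 223 of 7822 higher and 64 lower (median 0). By camera, upstream windows had an adjusted p = 3.15e-06, and an adjusted p = 0.146 with an estimated correlation.

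Some windows with the highest folds were nearly silent in Ws as well. The window upstream of GAE1, a UDP-glucuronate epimerase gene of cell wall synthesis (TAIR10, chromosome 4, 14884001 to 14884500), stood at 83.0 ± 5.76 CPM with AGO4-D742A and 0 in ago4-4, Ws and ago4-4/wtAGO4, at least 617-fold over ago4-4. A window downstream of AT1G12190 (chromosome 1, 4132001 to 4132500) was at least 956-fold higher, at 130 ± 31.2 CPM, with 0 reads in Ws. Of the 11 methylation targets, 1 rose and 0 fell, as was also so adjusted over the list alone. It was SUP, a zinc finger floral regulator (log2 change 4.22), with 262, 68 and 19 reads in the 3 libraries; without replicate 1 the log2 change was 2.74. FWA stood at 3.71 ± 0.562 CPM and AtMU1 at 15.4 ± 0.0661 CPM, and neither passed the test. Of 33 microRNAs 1 rose, miR319a by 0.67 (1 adjusted over the list alone), and of 7 TAS genes 0 passed the test (1 at an unadjusted p below 0.05 by edgeR). AGO4 was the only one of the 5 ARGONAUTE genes that passed. With TMM the split was 2826 higher and 1007 lower, and TMM moved the median of all features from 0.10 to -0.03 on the log2 scale and ended the call at miR319a (0.38). The lower count was 91 without ago4-4 replicate 2 and 114 without AGO4-D742A replicate 1.

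The transgenes were then set directly against each other in ago4-4. Relative to wtAGO4, 4193 features were lower and 2401 higher with AGO4-D742A. Upstream windows were lower at 1178 of 3863 and higher at 330 (median log2 change -0.36), and pseudogene windows were higher at 707 of 7822 and lower at 212 (median 0.33). A window over AT2G05410 (chromosome 2, 1977001 to 1977500) was at least 364-fold lower, from 78.6 ± 22.2 CPM, and one over AT5G22560 was at least 237-fold lower. The window upstream of GAE1 was at least 398-fold higher, and one over AT3G49450 at least 255.6-fold. AtMU1 was lower by 0.97 on the log2 scale, SUP was higher by 3.74 (2.26 without AGO4-D742A replicate 1) and EPF2 was higher by 0.68.

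Those 3 were the only ones of 11 methylation targets that passed; adjusted over the list alone FWA was also lower (log2 change -0.75, adjusted p = 0.0652 over all features). Of 33 microRNAs and 7 TAS genes 0 passed, either way of adjusting (3 and 0 at an unadjusted p below 0.05 by edgeR), and AGO4 was higher by 3.54. By camera, upstream windows had an adjusted p = 0.179 and pseudogene windows an adjusted p = 0.091 with an estimated correlation. DESeq2, which also scaled the libraries by its own size factors, gave 4532 lower and 1497 higher. The call at EPF2 ended without wtAGO4 replicate 1 (log2 change 0.54) or AGO4-D742A replicate 3 (0.62), with miRNA scaling (0.63) and with no filter (0.68, adjusted p = 0.0830).

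How far each transgene restored what ago4-4 had lost was counted over the 7656 features that fell in ago4-4. Of these, 6003 (78.4%) rose with wtAGO4 and 2609 (34.1%) with AGO4-D742A; 2395 rose with both, 3608 with wtAGO4 alone, 214 with AGO4-D742A alone and 1439 with neither. The summed level of the 7656 features was 131425 ± 6644 CPM in Ws and 28090 ± 2479 CPM in ago4-4 (SD, n = 3). It was 116591 ± 9380 CPM with wtAGO4 and 50007 ± 2839 CPM with AGO4-D742A, which is 85.6% and 21.2% of the way back to Ws. The gap between the transgenes cannot be assigned to slicing, because their protein levels were not measured. The 3179 features that rose in ago4-4 went from 43383 ± 3429 CPM in Ws to 84578 ± 7986 CPM in ago4-4. They stood at 50581 ± 3438 CPM with wtAGO4 and 84466 ± 4806 CPM with AGO4-D742A; 1842 of them fell with wtAGO4 and 95 with AGO4-D742A. Both feature sets were chosen on these same Ws and ago4-4 libraries, so the levels in those groups are not independent evidence. Independent lists would share 1832 and 1015 features. The covariance of log2 changes with ago4-4 against Ws was -3.41 for wtAGO4 and -1.51 for AGO4-D742A. It was -0.165 to -0.144 and -0.150 to -0.117 in 5 simulations. These drew the counts of all 21 libraries anew and gave both transgenic lines the means of ago4-4. No feature was called with wtAGO4 in those simulations, so they give no overlap of calls to compare with for it. Part of the excess may come from the shared ago4-4 libraries, which are too few to be split.

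**Figure D3:**
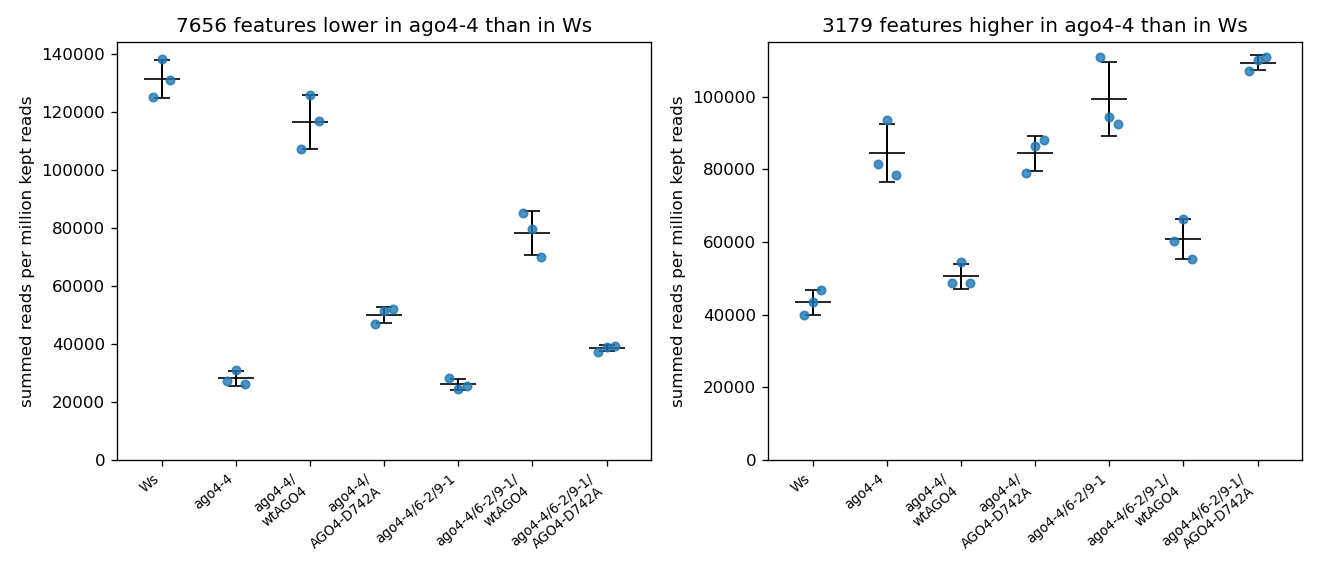
Summed CPM of the 7656 features that fell in ago4-4 (left) and of the 3179 that rose (right), with 1 point per library, a bar at the mean and error bars of 1 SD (n = 3) for each of the 7 groups; both axes start at 0. On the left the wtAGO4 libraries of ago4-4 lie near Ws at 116591 CPM, and the AGO4-D742A libraries lie at 50007 CPM.

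The triple mutant was set against ago4-4 to see what the further loss of AGO6 and AGO9 does. In the triple mutant 8340 features rose and 5057 fell. Pseudogene windows rose at 3365 of 7822 and fell at 730 (median log2 change 0.55), and pericentromeric windows rose at 5956 of 16764. The triple-mutant lines carried Col-0 alleles over most of the genome: 17.13% to 22.8% of reads over 18323 informative sites had the Ws allele in their 9 libraries, against 99.59% to 99.72% in the other 12. Of the 26336 tested windows, 22790 lay in 1 Mb bins where the compared libraries carried different alleles, so genotype and accession cannot be separated there. With those left out, 842 features were lower and 287 higher of 3602 tested. Of the 12 named windows, 11 lay in such bins. Among them, a window over AT3G44580 (TAIR10, chromosome 3, 16160001 to 16160500) stood at 246 ± 25.9 CPM in the triple mutant and 0 in ago4-4, and it was also near 0 in the other Ws-background lines.

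MicroRNAs changed in this comparison more than in any other: 13 of 33 fell and 4 rose (14 and 4 adjusted over the list alone). The compared lines also differ in accession, so changes in these microRNAs and in the listed genes cannot be assigned to the loss of AGO6 and AGO9. miR398b, which targets copper/zinc superoxide dismutase, fell by 3.77 on the log2 scale (-4.53 without triple-mutant replicate 3). miR408 fell by 2.62, miR403, which targets AGO2, by 1.13 and miR173, the trigger of TAS1 and TAS2 siRNAs, by 1.22. miR827 rose by 1.64 (0.96 without triple-mutant replicate 3). Of the 11 methylation targets, AtMU1 rose by 1.14, AtGP1 by 0.90 and QQS by 0.73 and FWA fell by 1.01, the same 3 and 1 adjusted over the list alone. TAS1A fell by 0.47 among 7 TAS genes (0 adjusted over the list alone), and AGO9 fell by 1.53 among 5 ARGONAUTE genes. The rise of pseudogene windows had an adjusted p = 0.112 with an estimated correlation. Scaling to microRNA reads gave 11933 higher and 3297 lower and moved the median of all features from 0.16 to 0.70 on the log2 scale; with it miR398b, miR408, miR403 and miR173 still fell, but the other 9 microRNAs, FWA, TAS1A and AGO9 did not pass, and miR319a turned from -0.42 to 0.05. Leaving out 1 library ended the calls of miR158a, miR166a, miR171a, miR319a, miR393a, miR822, miR824, FWA, QQS and TAS1A in at least 2 of 6 fits each; the values nearest 0 were 0.39, -0.40, -0.44, -0.35, -0.68, 0.31, -0.52, -0.59, 0.54 and -0.42, without ago4-4 replicate 3, triple-mutant replicate 3, triple-mutant replicate 2, ago4-4 replicate 2, triple-mutant replicate 2, triple-mutant replicate 3, triple-mutant replicate 2, ago4-4 replicate 2, ago4-4 replicate 3 and ago4-4 replicate 2. Calls of other microRNAs and listed genes held with TMM, DESeq2, no filter, 1 mismatch allowed, the replicate block and the 2 groups fitted alone, while each of these settings ended at least 1 of those 10.

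The wild-type transgene in the triple mutant raised 7988 features and lowered 2105. Upstream windows rose at 2232 of 3863 and fell at 127 (median log2 change 1.46), and pseudogene windows fell at 1035 of 7822 and rose at 484 (median -0.28). Reads at CML41, a calmodulin-like gene among the methylation targets, stood at 120 ± 60.3 CPM with wtAGO4, with 2199 reads against 3 in the triple mutant. The window over CML41 (TAIR10, chromosome 3, 18873501 to 18874000) was at least 798-fold higher, one over AT5G11370 (chromosome 5, 3629001 to 3629500) at least 605-fold and one over GH9B10, a glycosyl hydrolase family 9 gene (chromosome 2, 18390501 to 18391000), at least 562-fold. Of the named windows, 1 of 4 higher and 4 of 8 lower ones lay in bins where the compared libraries carried different alleles. The higher one was AT5G11370, in whose bin triple-mutant replicates 2 and 3 had 99.9% Ws alleles and replicate 1 had 0.127%, against 0.183% to 0.425% with wtAGO4. Its window held 0 reads in each triple-mutant library. FWA rose by 3.38, SDC by 0.53, and AtGP1 fell by 0.66, so that 3 of 11 methylation targets rose and 1 fell, as also adjusted over the list alone.

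AGO4 rose by 1.62 among 5 ARGONAUTE genes, miR398b fell by 1.59 among 33 microRNAs (0 adjusted over the list alone; -0.84 without triple-mutant replicate 3) and of 7 TAS genes 0 passed (0 at an unadjusted p below 0.05 by edgeR). In the bin of the miR398b gene (chromosome 5, from 4000001) the triple-mutant libraries had 1.51%, 100% and 99.4% Ws alleles, against 0% to 0.741% with wtAGO4. Replicate 1, with the alleles of the wtAGO4 libraries, stood at 3.61 CPM against 4.13 to 5.46 CPM there, so this fall cannot be assigned to the transgene. By camera, pseudogene windows had an adjusted p = 0.0343 and upstream windows an adjusted p = 0.0782 with an estimated correlation. The split was 6814 higher and 4711 lower with TMM and 6482 higher and 2895 lower with DESeq2, and TMM moved the median of all features from 0.21 to -0.03 on the log2 scale. The call at AtGP1 held only without triple-mutant replicate 3 (log2 change -0.69 to -0.50 in the other 5 fits). The call at SDC ended without triple-mutant replicate 1 or wtAGO4 replicate 1 (0.48 and 0.46) and with TMM (0.22), and that at miR398b also without wtAGO4 replicate 1 or 2 (-1.50 and -1.59). SDC did not pass with miRNA scaling (0.44) or DESeq2 (0.31) either. With no filter SDC and AtGP1 did not pass, and with the 2 groups fitted alone SDC, AtGP1 and miR398b did not. Without windows in bins with differing alleles, 7020 features were higher and 1934 lower.

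AGO4-D742A in the triple mutant raised 3863 features and lowered 907. Upstream windows rose at 908 of 3863 and fell at 121 (median log2 change 0.55; adjusted p = 0.343 with an estimated correlation), and gene bodies rose at 823 of 4853. A window over YUC2, an auxin biosynthesis gene (TAIR10, chromosome 4, 7724001 to 7724500), rose from 0.172 ± 0.197 to 27.2 ± 2.08 CPM, and one upstream of OXS2 (chromosome 2, 17488501 to 17489000) from 0.524 ± 0.375 to 94.9 ± 40.03 CPM. Their log2 changes of 7.08 and 7.40 became 8.22 without triple-mutant replicate 3 and 8.00 without triple-mutant replicate 1. The OXS2 window stood at 189 ± 30.3 CPM in Ws, and its bin had 6.37% to 11.1% Ws alleles with AGO4-D742A against 0.181% to 0.803% in the triple mutant. Of 11 methylation targets 3 rose and 0 fell (4 and 0 adjusted over the list alone, with SUP): FWA by 2.09, ROS1 by 1.36 and CML41 from 3 reads to 20. AGO4 rose by 2.75, TAS1B fell by 1.13 among 7 TAS genes (0 adjusted over the list alone) and of 33 microRNAs 0 passed, either way of adjusting (2 at an unadjusted p below 0.05 by edgeR). Of the 8 named windows that fell, 5 lay in bins where the compared libraries carried different alleles, and without such bins 414 features were lower and 3093 higher. The split was 2658 higher and 1607 lower with TMM and 2356 higher and 1184 lower with DESeq2, and TMM moved the median of all features from 0.27 to 0.00 on the log2 scale. The call at TAS1B was lost without triple-mutant replicate 1 (log2 change -0.30) and without each AGO4-D742A replicate (-1.13, -1.11 and -1.15), and with miRNA scaling (-1.06), the replicate block (-1.02), multi-mapping reads split and the 2 groups fitted alone (both -1.13). TAS1B stood at 539, 168 and 156 CPM in the triple-mutant libraries, whose bin (chromosome 1, from 18000001) had 4.69%, 99.7% and 99.8% Ws alleles. The call at CML41 was lost without triple-mutant replicate 2 or 3 and AGO4-D742A replicate 1 or 2 (adjusted p = 0.071, 0.0578, 0.0714 and 0.0624 by edgeR) and with TMM (adjusted p = 0.0552), and that at ROS1 without AGO4-D742A replicate 3 (1.08).

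Against wtAGO4 in the triple mutant, AGO4-D742A left 5751 features lower and 2761 higher. Upstream windows were lower at 1609 of 3863 and higher at 230 (median log2 change -0.80; adjusted p = 0.091 with an estimated correlation), and pseudogene windows were higher at 1193 of 7822 and lower at 396 (median 0.38; adjusted p = 0.0453 with an estimated correlation). CML41 was lower by 6.59 on the log2 scale and FWA by 1.28, and AtGP1 was higher by 1.00, so that 2 of 11 methylation targets were lower and 1 higher, as also adjusted over the list alone. A window over AT1G23240 (chromosome 1, 8254501 to 8255000) was at least 527-fold lower, from 94.2 ± 14.2 CPM, and one upstream of GH9B6, a glycosyl hydrolase family 9 gene (chromosome 1, 8238001 to 8238500), at least 291-fold. Both lay in a bin with 22.2% to 24.2% Ws alleles with AGO4-D742A against 0.817% to 1.69% with wtAGO4, and both had 0 reads in Ws. Of 33 microRNAs, miR163 was higher by 1.03 and miR398b by 1.86 (1 adjusted over the list alone). The bin of the miR163 gene (chromosome 1, from 24000001) had 99.8% to 99.9% Ws alleles with wtAGO4 and 0.2459% to 0.3402% with AGO4-D742A, so the difference at miR163 cannot be assigned to the transgene. AGO4 was higher by 1.13 and AGO6 by 1.58. TAS1B was lower by 1.63, but wtAGO4 replicate 3, at 128 CPM, stood apart from replicates 1 and 2 (572 and 521 CPM) and near the AGO4-D742A libraries (132, 128 and 135 CPM). Ws alleles in its bin followed the same split, with 7.97%, 5.98% and 99.9% in the wtAGO4 libraries and 99.8% to 99.9% with AGO4-D742A, so the difference cannot be assigned to the transgene. Of the named windows, 4 of 4 higher and 4 of 8 lower ones lay in bins where the compared libraries carried different alleles, and without such bins 4272 features were lower and 2240 higher. The call at miR398b was lost without wtAGO4 replicate 1 (1.76) or AGO4-D742A replicate 1 (1.64), and that at AGO6 without AGO4-D742A replicate 2 (1.39).

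The effects in the single and triple mutants overlapped. Of the 6315 features that rose with wtAGO4 in ago4-4, 4609 also rose with wtAGO4 in the triple mutant, against 1911 for independent lists. Of the 3499 that rose with AGO4-D742A in ago4-4, 1397 also rose in the triple mutant, against 512. The effect of wtAGO4 differed between the 2 backgrounds at 2272 features by an interaction test, and the difference between AGO4-D742A and wtAGO4 did so at 2557. The 2 backgrounds also differ in accession, so these counts do not isolate the loss of AGO6 and AGO9.

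**Figure D4:**
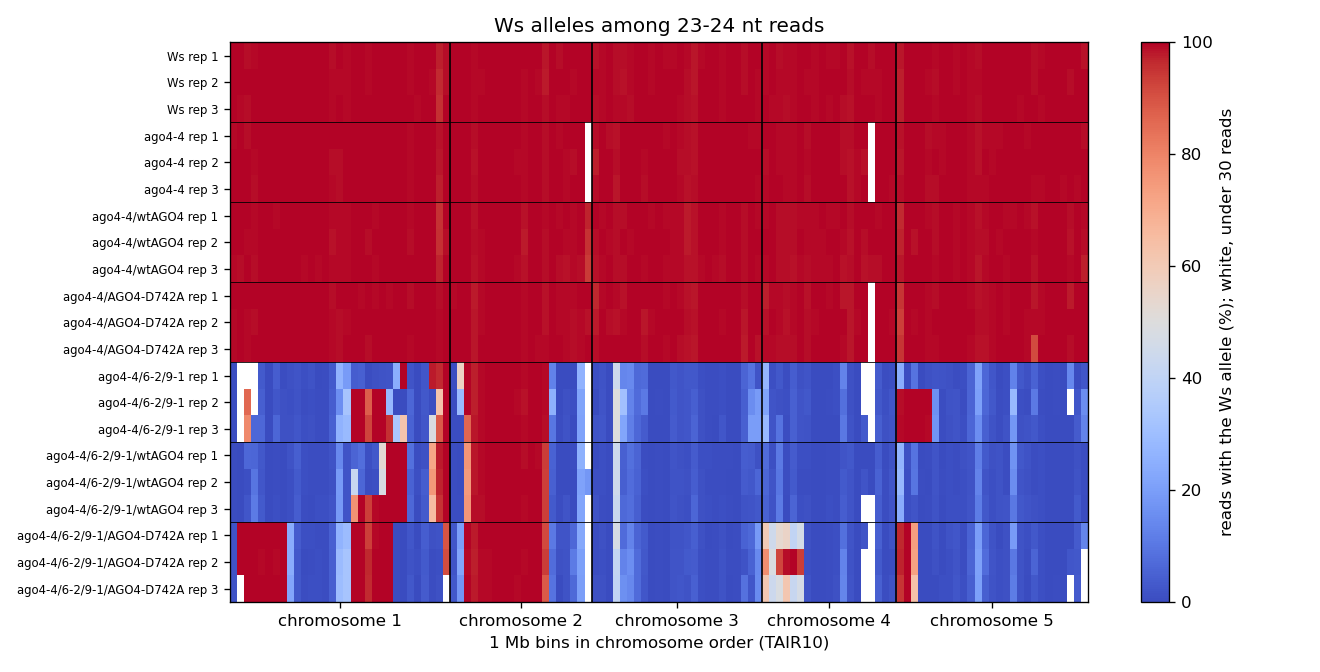
Each row is 1 of the 21 libraries and each column a 1 Mb bin along chromosomes 1 to 5 (TAIR10); colour gives the percent of 23 to 24 nt reads over informative sites that carry the Ws allele, and white marks bins with under 30 reads. The 9 libraries of triple-mutant lines are mostly blue (17.13% to 22.8% Ws alleles overall) except for segments such as that around AGO4 on chromosome 2, and they differ from each other on chromosomes 1, 4 and 5 and in a bin near the start of chromosome 2.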

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

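The tests of chromosome segments, of the perfect-match rule and of other groupings of the libraries were chosen after the results they bear on were seen.

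The effect of wtAGO4 differed between the single and the triple mutant at 2272 features by the interaction test of edgeR, 955 lower and 1317 higher in the triple mutant. Windows upstream of genes were lower at 218 and higher at 307 (median log2 difference 0.34). Among the methylation targets, FWA gained more in the triple mutant (1.78, adjusted p = 0.0120). AtMU1 differed by -1.32 (adjusted p = 0.00162) and did not rise with wtAGO4 in the triple mutant. Its level there was 35.3, 38.8 and 26.2 CPM without a transgene, against 24.8, 25.9 and 29.3 CPM with wtAGO4. CML41 also passed (adjusted p = 0.00275), with 2199 reads with wtAGO4 in the triple mutant and 0 in the single; Ws held 3, so an accession difference stays open for it. Of 33 microRNAs and 7 TAS genes, 0 differed (2 and 0 at an unadjusted p below 0.05 by edgeR). Without windows in bins where alleles differ among the triple-mutant lines, 1797 features differed, but those lines still differ from ago4-4 in accession over most bins. Outside bins whose alleles spanned over 50 points in any comparison with a triple-mutant line, 216 of 3458 features differed. These features still include bins that differ by less or hold too few reads, and the listed genes and microRNAs. Accession is therefore not fully removed for them. Elsewhere the difference may come from accession or from the loss of AGO6 and AGO9. In 1 of 50 regroupings drawn from 163, the real one, were as many features called, and the highest of the others was 59. Each other regrouping mixed lines within its groups, which widens the spread and keeps calls few. The regroupings therefore cannot exclude chance.

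The difference between AGO4-D742A and wtAGO4 also differed between the backgrounds, at 2557 features, 1622 lower and 935 higher in the triple mutant. Upstream windows were lower at 431 and higher at 206 (median -0.40), and pseudogene windows at 138 and 151 (median 0.00). AGO4 itself differed by -2.41 (adjusted p = 5.4e-05) and AtMU1 by 1.30. Without bins that differ among the triple-mutant lines, 1716 features differed, and accession is not removed by this. Outside bins whose alleles spanned over 50 points in any comparison with a triple-mutant line, 296 of 3458 features differed. Accession is not fully removed for these, and elsewhere it stays open. In 1 of 50 regroupings, the real one, were as many called, and the highest of the others was 0. The others again mixed lines within their groups, so they cannot exclude chance.

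Alleles of the Col-0 reference made up at least 77.2% of the informative reads in each of the 9 triple-mutant libraries, against at most 0.34% in Ws. Ws alleles filled chromosome 2 around AGO4. The 8340 features higher in the triple mutant than in ago4-4 may largely reflect these segments: the share of windows called higher was 4.32 times as large where alleles differed as where they agreed (35.3% and 8.16%). Perfect matching kept 75.7% to 82.8% of reads in the Ws-background groups and 85.2% to 88.8% in the triple-mutant groups. With 1 mismatch allowed, 8299 features were higher and lower ones went from 5057 to 6388. In each other comparison the higher count rose with this setting. Reads with more mismatches or with gaps still went unmatched, so loss of Ws reads by perfect matching stays open as a cause. The loss of AGO6 and AGO9 stays open for these features.

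The same may hold for part of the 907 features lower with AGO4-D742A in the triple mutant. The share of windows called lower was 5.15 times as large in bins where alleles differed (9.26% against 1.80%). In bins where alleles agreed, 318 windows were lower. The share of Ws alleles is averaged over a bin, so a short segment can lie within a bin counted as agreeing. Segments therefore cannot be excluded for those 318 windows. An effect of the transgene also stays open for them.

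With 3 libraries against 3, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split and the highest other called 10835 and 0 features for ago4-4 against Ws, 8836 and 0 for wtAGO4 against ago4-4, 3687 and 0 for AGO4-D742A against ago4-4, and 6594 and 0 for AGO4-D742A against wtAGO4. They called 13397 and 1 for the triple mutant against ago4-4. Within the triple mutant they called 10093 and 244 for wtAGO4, 4770 and 5 for AGO4-D742A, and 8512 and 3 for AGO4-D742A against wtAGO4. In each case 1 split, the real one, gave as many.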

How the results depend on the processing

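Some alternatives leave out windows with differing alleles in the compared lines or between the backgrounds, or leave out 3 triple-mutant libraries. They were chosen after the data were seen. Windows of 1000 bp, 1 mismatch allowed and the replicate block each left all 16, 16 and 20 counts within 1.5 times. The replicate block gave 7567 lower and 3057 higher features for ago4-4 against Ws, and replicate numbers did not pair the libraries: correlations of matched changes lay between -0.0745 and 0.187. Of 2692 values for the named features, 2522 kept their direction and call, 169 lost the call and 1 reversed, miR319a in the triple mutant against ago4-4 (0.0459 with microRNA scaling). In simulations edgeR found 10.4% of 2-fold changes; whether depth or replicate spread limits this was not tested. Except where fewer or more features were tested, the cause was not tested.

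Leaving out 1 library gave 2099 to 3072 higher features for ago4-4 against Ws (2099 without ago4-4 replicate 2). It gave 1501 to 2421 lower for wtAGO4 against ago4-4 (1501 without ago4-4 replicate 2, 1611 without wtAGO4 replicate 1) and 91 to 187 lower for AGO4-D742A against ago4-4 (91 without ago4-4 replicate 2, 114 without AGO4-D742A replicate 1). The F ratio ranged from 6.41 to 11.7 for the 24 nt share and from 84.1 to 229 for the first A.

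In what follows, S is ago4-4 and T the triple mutant. With at least 2-fold change, 1646 features were lower for S/wtAGO4 against S, 119 for S/AGO4-D742A against S and 1222 for T/wtAGO4 against T, and 1754 were higher for T/AGO4-D742A against T/wtAGO4. With an estimated correlation, 4 window class results were called. TMM gave 5396 higher for S against Ws, and lower counts of 4294 for S/wtAGO4 against S, 1007 for S/AGO4-D742A against S, 4711 for T/wtAGO4 against T and 1607 for T/AGO4-D742A against T. MicroRNA scaling gave lower counts of 1374 for S/wtAGO4 against S, 89 for S/AGO4-D742A against S and 3297 for T against S. DESeq2 gave 325 lower for S/AGO4-D742A against S, 1497 higher for S/AGO4-D742A against S/wtAGO4 and 2356 higher for T/AGO4-D742A against T. With only the compared groups fitted (20253 features), T/AGO4-D742A against T had 537 lower and 2401 higher.

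With no filter (197807 features), 1896 were higher for S against Ws, 1230 lower for S/wtAGO4 against S, 114 lower for S/AGO4-D742A against S and 1830 higher for T/AGO4-D742A against T/wtAGO4. With a mean of at least 50 counts (4691 features), lower and higher were 1958 and 802 for S against Ws, 673 and 1708 for S/wtAGO4 against S, 92 and 1020 for S/AGO4-D742A against S, and 1305 and 754 for S/AGO4-D742A against S/wtAGO4. They were 1600 and 1443 for T against S, 815 and 2067 for T/wtAGO4 against T, 293 and 1459 for T/AGO4-D742A against T, and 1572 and 1055 for T/AGO4-D742A against T/wtAGO4. With multi-mapping reads split over their places (39715 features), they were 12222 and 5898 for S against Ws, 4934 and 10660 for S/wtAGO4 against S, 409 and 6546 for S/AGO4-D742A against S, and 7118 and 3786 for S/AGO4-D742A against S/wtAGO4. They were 4332 and 12504 for T/wtAGO4 against T, 1371 and 6550 for T/AGO4-D742A against T, and 9460 and 5502 for T/AGO4-D742A against T/wtAGO4. Without windows in bins with differing alleles, T against S had 842 lower and 287 higher and T/AGO4-D742A against T had 414 lower. Without windows in bins with differing alleles in any comparison with a triple-mutant line (3458 features left), the interactions had 216 and 296. Without 3 libraries of other segments, 1390 were lower for T/wtAGO4 against T and 583 for T/AGO4-D742A against T, and calls ended at SDC and AtGP1 for the first (log2 change 0.52 and -0.52), at ROS1 and TAS1B for the second (1.23 and -0.28), at AGO6 for T/AGO4-D742A against T/wtAGO4 (1.28), and at miR171a, miR822, miR824 and FWA for T against S (-0.46, 0.65, -0.71 and -0.94). Without windows in bins with differing alleles, where only the adjustment changes, calls ended at miR171a, miR319a, miR822 and miR824 for T against S and at TAS1B for T/AGO4-D742A against T.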

Other observations

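The tests of microRNA scaling, of the ago4-4 libraries and of carry-over were chosen after the results were seen; those of depth and of a linked chromosome segment were written before.

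Some small RNAs were higher in ago4-4 with AGO4-D742A than in each other Ws-background line. At 795 features reads were higher with AGO4-D742A than in Ws, ago4-4 and ago4-4/wtAGO4 alike, against 25 that were higher with wtAGO4 than in Ws, ago4-4 and ago4-4/AGO4-D742A. Of the 795, 299 lay over gene bodies, 194 upstream of genes and 52 over pseudogenes, and 130 had no read in the other 3 lines. Windows upstream of GAE1 and beside AT1G12190 are examples, and in the triple mutant with AGO4-D742A they stood at 1.16 ± 0.0945 and 2.31 ± 0.184 CPM (SD, n = 3). CML41 had 2199 reads in the triple mutant with wtAGO4, and 0 in ago4-4 with wtAGO4 or with AGO4-D742A.

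A candidate explanation for the 795 features is a chromosome segment linked to the transgene, but chromosome 1, with the most, held 28.5% of them and 21.6% of all tested windows. Carry-over of reads between the AGO4-D742A lines could place such reads in the triple mutant. Of 36 Ws windows absent from the triple mutant with and without wtAGO4, 52.8% had no read in the triple mutant with AGO4-D742A. Carry-over at the level seen, 1.15% of the ago4-4/AGO4-D742A level, would leave 2.13%. That level was taken as the same for all windows, so lower or uneven carry-over is not excluded. Of the 795, 104 were also higher with AGO4-D742A than in the triple mutant with and without wtAGO4, against 21.8 for independent lists. An effect of the AGO4-D742A protein or of its higher small RNA level at AGO4 stays open. Lower or uneven carry-over also stays open for the reads in the triple mutant and for this overlap.

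Pseudogene windows were higher in ago4-4 than in Ws, with a median log2 change of 0.37. A smaller total of other 24 nt reads could raise their share, but the median was 0.31 with microRNA scaling (0.314), and it was 0.330 after thinning each library to 3736855 reads, which argues against depth. A fault of the ago4-4 libraries is argued against by the triple mutant, where wtAGO4 lowered the same class (median -0.285). The set test held with an estimated correlation (adjusted p = 0.0343). No biological explanation was tested.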
